A study of Mus musculus with 3 samples.

How the data were processed

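RNA from the CA1 field of the mouse hippocampus was measured on 3 one-colour oligonucleotide arrays, 1 per sample. Per the labels, young male C57BL/6J mice went through contextual fear conditioning, and total RNA was taken 4 h after the last shock. The 3 samples form 1 group, and no control group was analysed here, so no comparison between groups was possible. The labels number the samples and do not say whether each is 1 animal or a pool. Spread between samples may therefore be technical as well as biological.

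The authors deposited 1 linear intensity for each of 12488 probe sets on each array. In the deposited values the mean intensity without the highest and lowest 2% was 500.3 on all 3 arrays, which shows that the arrays had been brought to a common trimmed mean. The software that made the intensities was not given in the sources used here. The medians of the deposited intensities were 189.2, 170.1 and 196.4 on arrays 1, 2 and 3. The table holds no detection calls and no background measurement, so no probe set is called present or absent here.

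Gene names came from the GEO platform annotation, dated 2016, in which 10833 probe sets outside the 66 controls have 1 gene symbol and 396 have several. Another 1193 were not listed there and are unnamed here. Probe sets with several symbols were not named. Gene IDs of 10817 probe sets matched a RefSeq gene table of the mouse assembly GRCm38.p6, 16 did not, and the match changed 0 symbols. That table served for names and for the span of each gene, and no coordinates are printed.

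From the deposited intensities the control probe sets were removed. Each array was divided by its own median over named probe sets and multiplied by the mean of the 3 medians, which are the factors 0.996, 1.077 and 0.937 (log2 shifts of -0.01, 0.11 and -0.09). Against unscaled values the median of array 2 thus lies 0.11 higher, and departures of gene lists are given net of random lists for that reason. Values under 36.5, the 20th percentile of all scaled values, were then set to that floor, which took 19.7%, 21.5% and 18.8% of the probe sets of arrays 1, 2 and 3. Values were then converted to log2 by the present re-analysis, because the deposited values were not logs. For a gene with several probe sets (2073 of 8251 genes) the probe set with the highest mean log2 value was used. Some of the probe sets used are, by their names, of a shared or cross-matching type and may read other transcripts as well. Those of Plk3, Chgb, Cpe, Penk, Ptgds, Col1a2, Hcn2 and Dnm1 are among them. A probe set or gene is called measured where its mean lies above the median of all probe sets, an intensity of 172.3.

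Before the data were examined, 33 gene lists were fixed for cell types and pathways, together with the scaling, the floor, the thresholds and the rule for named genes. Of the 1095 entries in these lists 802 were on the array, and 32 lists had at least 5 genes there. The wording fixed beforehand asked for at least 5 measured genes. The minimum was applied here to genes on the array instead. The GABA-A receptor list, with 3 measured genes, was therefore kept although it falls short of that wording. For each list and array the level is the median over its genes minus the median of all genes, set against 10000 random lists of the same size. The spread of a list is the median SD over its genes. Its departure on an array is the median, over its genes, of that array minus the mean of the other 2 arrays. Spread and departure were set against 10000 random lists matched on mean level in 20 classes, leaving out genes at the floor on all 3 arrays. A list is said to stand out at or beyond the 1st or the 99th percentile. Of 96 list and array pairs, 1.9 would lie beyond these limits by chance for independent lists. These percentiles describe the 3 arrays and are not p-values, because genes are not replicates. Probe sets bind their targets with different strength, so the level of a list depends on its probe sets as well as on its transcripts.

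Named genes were chosen by a fixed rule. It takes the 3 members of each list with the highest mean level and the measured member with the largest SD, and up to 6 members by level in the immediate early, late plasticity-associated and NF-kappaB lists. It also takes the 5 highest and 5 lowest measured genes by departure on each array, and the sex-linked check genes. Genes outside the rule are marked as chosen after their values were seen.

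The list statistics were tested on 20 simulated sets of 3 arrays with 8251 genes each, at 1000 random lists. With no shift, 1.9 list and array pairs lay beyond the limits on average and 6 at most. A log2 shift of 0.4 on 1 array was found in 20 of 20 sets for general neurons, 20 of 20 for oligodendrocytes and 19 of 20 for interneurons. A doubled spread of the proteasome list was found in 20 of 20 sets. These simulations draw genes independently, and genes of a real list vary together, so chance may exceed these figures on the real arrays. Alternatives were no scaling, quantile normalization, other floors and filters, other rules for 1 value per gene, random lists not matched on level, a 1.5-fold limit, and leaving out each replicate. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. With 3 arrays, their number limits the precision of every value.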

Results

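Transcript levels were measured in 3 samples of CA1, the hippocampal field whose pyramidal neurons form the main output of the hippocampus. Contextual fear conditioning pairs a place with foot shock so that the animal later fears the place. Here a mouse spent 2 min in a new chamber before a shock of 0.5 mA lasting 1 s, 3 shocks were given in all, and the return to the home cage came 1 min after the last. RNA was collected at 4 h. All 3 samples belong to this group, so the data give the levels of genes after conditioning and the spread between samples, and no change caused by conditioning. Intensities are scaled values, given as mean ± SD over the 3 samples (n = 3), and levels of gene lists are log2 relative to the median gene of the array.

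The CA1 pyramidal, general neuron and astrocyte lists lay above the 99th percentile of random lists in all 3 samples, while the dentate granule and vascular lists lay inside the range of random lists. The CA1 pyramidal list stood at 2.09 ± 0.11, with 9 of its 10 genes measured, and held Ccn3 (3764 ± 712), Wfs1 (2702 ± 601), which encodes an endoplasmic reticulum membrane protein, and Dkk3 (2228 ± 970). Markers of the neighbouring CA3 and CA2 fields stood at 1.49 ± 0.18 with 5 of 9 measured, led by Rgs14 at 5208 ± 580, a regulator of G protein signalling, with Nnat at 2229 ± 2303 and Ptpn5 at 1036 ± 160. Dentate granule markers stood at -0.65 ± 0.10 with 5 of 12 measured, among them Calb1 (1626 ± 126), Marcks (1227 ± 137) and Btbd3 (475 ± 159). Markers of striatum, thalamus and cortex stood at -0.70 ± 0.15, with 9 of 19 measured, including the opioid precursor Penk (2001 ± 502), Fezf2 (1954 ± 469) and Tbr1 (1059 ± 82.1). Differences in level between lists each had an exact two-sided p of 0.25, the lowest that 3 samples allow. They are not read further, because probe sets bind unequally.

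General neuronal genes stood at 3.43 ± 0.14 (24 of 28 measured), with the endocytic GTPase Dnm1 at 27127 ± 4257, the vesicle fusion protein Snap25 at 17926 ± 2989 and the surface glycoprotein Thy1 at 14311 ± 574. The GABAergic interneuron list stood at 0.22 ± 0.08 (16 of 23), and its brightest members were the neuropeptides Cck at 16045 ± 1164 and Sst at 11176 ± 387 and Gad1, which makes GABA, at 3955 ± 637. Astrocyte genes stood at 2.52 ± 0.21 (21 of 22), with the metal-binding Mt3 at 23050 ± 2019, the lipid carrier Apoe at 22572 ± 4622 and Cpe at 20055 ± 1117. Oligodendrocyte genes stood at 1.61 ± 0.32 (15 of 18), with the myelin genes Mobp at 14626 ± 3638 and Mbp at 7446 ± 1048, and Qdpr at 4959 ± 1608.

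Microglial genes stood at -0.38 ± 0.26 (16 of 29), with the lysosomal protease Ctss at 2619 ± 86.1, the growth factor receptor Csf1r at 1624 ± 138 and the complement gene C1qc at 1521 ± 241. Endothelial and pericyte genes stood at -0.68 ± 0.12 (14 of 30), led by Bsg (2975 ± 2076), Pltp (892 ± 364) and Eng (827 ± 98.7). Choroid plexus and ependymal markers stood at -1.35 ± 0.34 (7 of 18), with Igf2 at 1541 ± 487, Msx1 at 513 ± 246 and Col9a3 at 409 ± 72.4. Meningeal and fibroblast markers stood at -0.80 ± 0.33 (13 of 27), with the prostaglandin D synthase Ptgds at 6900 ± 2301, Col1a2 at 2438 ± 434 and Dcn at 2243 ± 534. Blood cell markers were the dimmest list at -1.67 ± 0.53 (5 of 19), with the globin genes Hba-a1 at 2506 ± 522 and Hbb-b2 at 382 ± 28.6, and Ighm at 558 ± 44.6. Of the sex-linked genes, Xist lay at the floor on arrays 1 and 3 and at 41.8 on array 2, while Eif2s3y was at 182 ± 59.6 and Uty at 114 ± 23.2, in samples labelled male. Kdm5d lay at the floor on arrays 1 and 3 and at 76.0 on array 2. Uty and Kdm5d were below the limit for measured genes. Eif2s3y was at 115 on array 3, also below that limit, and its probe set is of shared or cross-matching type.

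**Figure D1:**
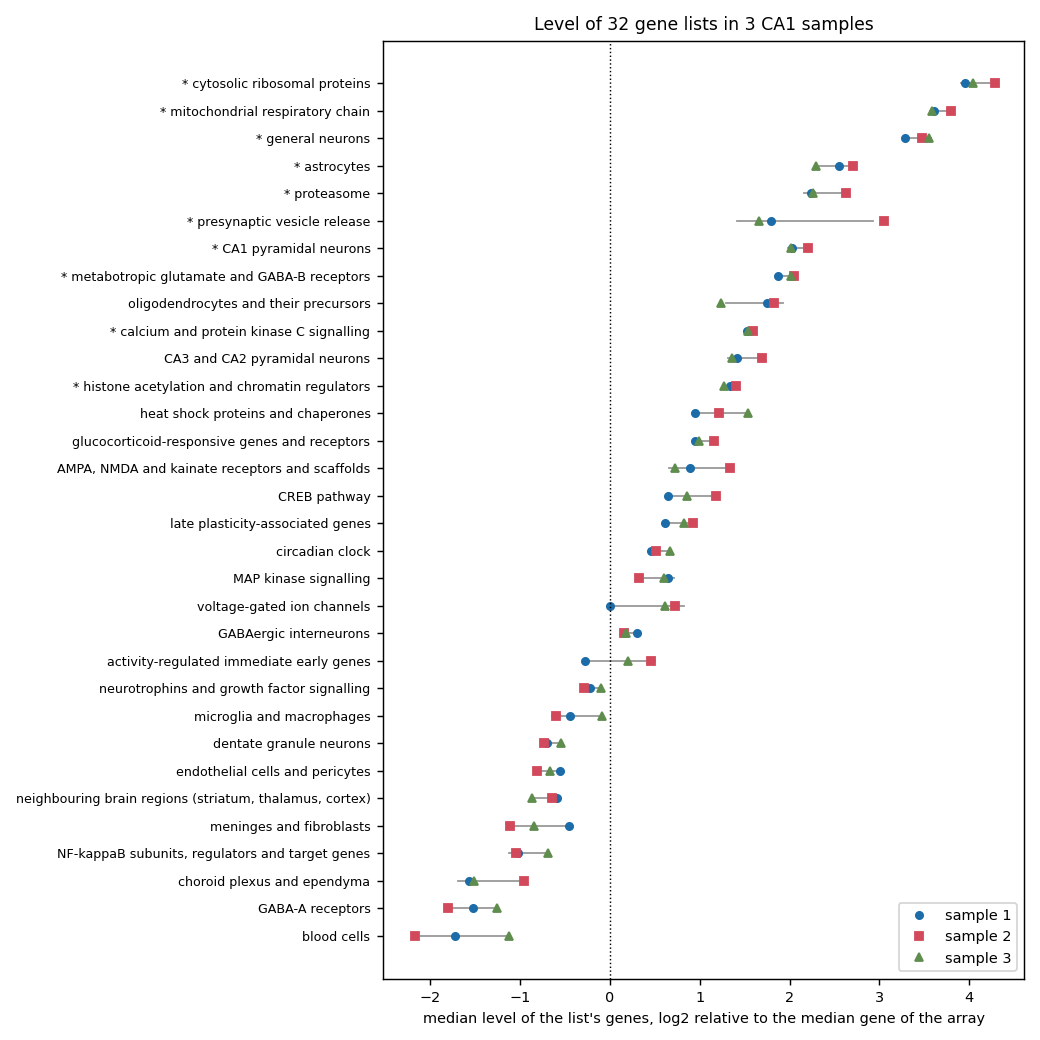
Median level of each of 32 gene lists (horizontal axis, log2 relative to the median gene of the array) in the 3 CA1 samples (symbols), with a line for the mean ± SD over the 3 samples; an asterisk marks the 10 lists at or above the 99th percentile of random lists on all 3 arrays. Ribosomal, respiratory chain and general neuron lists are brightest, at 4.09, 3.67 and 3.43, and the blood cell list is dimmest, at -1.67.

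The immediate early list, many but not all of whose members are transcribed within minutes of stimulation, stood at 0.13 ± 0.37 with 16 of 27 genes measured. Its brightest members were Jund (16981 ± 2447), Egr1 (1851 ± 140), the phosphatases Dusp6 (1162 ± 341) and Dusp1 (722 ± 76.7), Klf10 (851 ± 154) and Btg2 (704 ± 183). Egr1 varied by an SD of 0.11 on the log2 scale, while Junb was at 80.9, 807 and 406 on arrays 1, 2 and 3, and its other probe set did not single out the same array in the same direction. The late plasticity-associated list stood at 0.78 ± 0.16 (21 of 28), with the secretory granule protein Chgb at 10804 ± 1168, the activity-regulated kinases Plk2 at 7479 ± 1758 and Plk3 at 6630 ± 536, and Nrgn at 4612 ± 935. The neurotrophin Bdnf was at 2236 ± 504 and the endoplasmic reticulum chaperone Hspa5 at 2126 ± 559. The NF-kappaB list stood at -0.92 ± 0.20 (15 of 32), led by the survival gene Bcl2l1 (1661 ± 324), the subunit Rela (1236 ± 123), the inhibitors Tnip1 (851 ± 64.9), Nfkbib (765 ± 78.3) and Nfkbia (741 ± 66.7), and Sod2 (436 ± 41.6). None of these 3 lists stood outside random lists in level on all 3 arrays.

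Of the signalling and synaptic lists, 3 were above the 99th percentile of random lists on each array. The calcium and protein kinase C list stood at 1.55 ± 0.03 (23 of 29) and the metabotropic glutamate and GABA-B receptor list at 1.98 ± 0.10 (9 of 14), which are 2 of the 3. Their brightest genes were the kinase Prkcb (18823 ± 2801), the calcium sensor Hpca (14502 ± 4038), the calcineurin subunit Ppp3r1 (13004 ± 3843), the G protein subunits Gnao1 (13936 ± 1493) and Gnai2 (13926 ± 1462), and Gng3 (9442 ± 1798). The CREB pathway list stood at 0.90 ± 0.26 (16 of 23), with Gnas at 41647 ± 5311 and the protein kinase A subunits Prkar1a at 11283 ± 1657 and Prkar1b at 6269 ± 2123. The presynaptic list stood at 2.17 ± 0.76 (27 of 30), which is the other, and included the vesicle protein Vamp2 at 11493 ± 1783. AMPA, NMDA and kainate receptors with their scaffolds stood at 0.98 ± 0.32 (16 of 22), led by Gria2 (10429 ± 1797), Nsf (8798 ± 3065) and Gria1 (6499 ± 3360). Voltage-gated channels stood at 0.44 ± 0.39 (20 of 29), with Kcnab2 at 3300 ± 1915, Kcnma1 at 2287 ± 324 and Hcn2 at 2128 ± 29.7. GABA-A receptors stood at -1.53 ± 0.27 with 3 of 11 measured, namely Gabrb1 (5534 ± 610), the anchoring protein Gphn (738 ± 97.3) and Gabra2 (625 ± 387).

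Of the housekeeping lists, ribosomal proteins stood at 4.09 ± 0.18 (22 of 28), with Rpl41 at 61549 ± 2963, Rps28 at 31520 ± 3678 and Rps24 at 27334 ± 2133. The respiratory chain stood at 3.67 ± 0.11 (45 of 49), with Cox6a1 at 22680 ± 2255, Cyc1 at 12652 ± 1878 and Ndufb5 at 12523 ± 880, and the proteasome at 2.38 ± 0.22 (31 of 36), with Psmb1 at 5346 ± 172, Psma3 at 5103 ± 57.8 and Psmd1 at 4411 ± 679. Glucocorticoid-responsive genes stood at 1.04 ± 0.11 (24 of 30), with the metallothioneins Mt2 at 16691 ± 822 and Mt1 at 12022 ± 764, and Klf9 at 4557 ± 122. In all, 10 of 32 lists were at or above the 99th percentile of random lists on all 3 arrays and 0 were at or below the 1st. With the mean of a gene's probe sets the metabotropic and the chromatin lists were no longer among them, and without probe sets of shared or cross-matching type the astrocyte, calcium and chromatin lists were not, while the oligodendrocyte list was.

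Across 12422 probe sets, Pearson's r of log2 intensities was 0.938 for samples 1 and 2, 0.936 for samples 1 and 3 and 0.933 for samples 2 and 3, with Spearman's rho of 0.917, 0.914 and 0.911. These are correlations across probe sets, which are not independent replicates, and they contain the fixed differences between probe sets and the values at the common floor. Among 6211 measured probe sets the median SD was 0.27 on the log2 scale, and 889 (14.3%) differed by over 2-fold between the highest and lowest sample. Sample 2 was the farthest from the others in 445 of these, sample 1 in 223 and sample 3 in 221. Sample 2 was higher in 309 and lower in 136 of its 445, but unscaled values gave 204 higher and 239 lower, and quantile normalization 207 and 170. For sample 3 the scaled values gave 50 higher and 171 lower, unscaled values 104 and 115, and quantile normalization 85 and 140.

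The general neuron, presynaptic and glutamate receptor lists were higher in sample 2 than in the other samples. The general neuron list departed there by 0.58, against 0.12 for level-matched random lists, and 24 of its 28 genes were higher. The presynaptic list departed by 0.50 against 0.13 (26 of 30 higher), and the AMPA, NMDA and kainate list by 0.47 against 0.10 (20 of 22 higher), while 62.8% of all measured genes were higher on array 2 after scaling. Counted against the median of their class of level instead, 23 of 28, 21 of 30 and 19 of 22 genes were higher. That count was chosen after the results were seen. The vesicle protein Syp, the widest measured member of the general neuron and presynaptic lists, was at 495, 2176 and 479 on arrays 1, 2 and 3. Dnm1, the brightest member of both lists, was among the genes that were not higher on array 2 (31307, 22797 and 27277). The AMPA receptor subunit Gria1 was at 3106, 9826 and 6566. Gria1 departed more on array 1 (-1.37) than on array 2 (1.12), and its other probe set did not single out the same array in the same direction. Other neuronal lists stayed within the limits on array 2, with net departures of 0.08 for CA1 pyramidal neurons, 0.05 for CA3 and CA2, 0.09 for dentate granule neurons, 0.17 for interneurons, 0.11 for calcium and protein kinase C, 0.28 for metabotropic and GABA-B receptors, 0.05 for GABA-A receptors and 0.21 for voltage-gated channels. The net departures of 0.46, 0.37 and 0.36 lay past the 99th percentile of random lists in the scaled values, with no scaling and with quantile normalization. The general neuron and presynaptic lists share 9 genes, and without the shared genes the presynaptic list still departed by 0.37 net of random lists, a check chosen after seeing the data. With measured genes above the 75th percentile only, the AMPA, NMDA and kainate list departed by 0.20 net, at percentile 92.5. The control probe sets for Gapdh gave a 3' to 5' intensity ratio of 1.19 on array 2, against 4.85 on array 1 and 4.47 on array 3, and those for Actb gave 1.93 against 2.48 and 2.57, while those for Pcx gave 3.71 against 11.3 and 3.19.

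Chaperones were lower in sample 1 than in the other samples. The heat shock and chaperone list, at a level of 1.23 ± 0.30 with 30 of 35 genes measured, departed on array 1 by -0.41 against 0.00 for random lists, and 8 of 34 genes were higher there. The constitutive chaperone Hspa8 was at 4250, 6558 and 5037 on arrays 1, 2 and 3, the mitochondrial chaperonin Hspd1 at 5421, 7150 and 5593, Hsp90aa1 at 16680, 19153 and 19739, and the co-chaperone Stip1 at 187, 543 and 107. The list lay at or below the 1st percentile on array 1 with each scaling, floor, filter and probe set rule tried, and without sample 2 or sample 3. It also departed on array 2 by 0.36 against 0.11 (27 of 34 higher), at percentile 99.7, but without sample 1 that departure was 0.01 net, at percentile 56.0. With measured genes above the 75th percentile only, the departure on array 2 was 0.12 net, at percentile 87.9. On array 1 the 3' to 5' ratio of control probe sets was also the highest for Gapdh and Pcx, but not for Actb. General neurons and chaperones were also the 2 lists with wide spread for their level, with a median SD of 0.37 against 0.24 in random lists and 0.38 against 0.27. The chaperone list kept this standing with a floor at the 40th percentile, with no filter and without sample 3 but in no other alternative. The presynaptic list, at percentile 98.9, passed the limit with no scaling, both other floors, the mean of probe sets, no filter, and without sample 1 or sample 3. General neurons lost their standing with random lists not matched on level and without sample 2.

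General neuron, voltage-gated channel and late plasticity-associated lists were also lower in sample 1. General neurons departed there by -0.28 against 0.01 (5 of 28 higher), voltage-gated channels by -0.35 against 0.01 (7 of 27 higher) and late plasticity-associated genes by -0.29 against 0.00 (7 of 28 higher). Other neuronal lists stayed within the limits on array 1. Their net departures were -0.21 for CA1 pyramidal neurons, -0.11 for CA3 and CA2, -0.03 for dentate granule neurons and -0.07 for interneurons. Those of synaptic and signalling lists were -0.17 (presynaptic, percentile 1.07), -0.19 (AMPA, NMDA and kainate), -0.07 (calcium and protein kinase C), -0.06 (metabotropic and GABA-B) and -0.14 (GABA-A). Bdnf was at 1708, 2711 and 2288 on arrays 1, 2 and 3 and Nrgn at 3538, 5243 and 5056. Nptx1, a secreted protein that clusters AMPA receptors, was at 499, 1500 and 536, so sample 2 lay farthest from the others for it. The departures of the general neuron, channel and late plasticity lists depended on single samples. Without sample 2 general neurons departed by -0.09 net (percentile 14.3) and voltage-gated channels by -0.26 net (percentile 1.2), and without sample 3 the late plasticity list departed by -0.15 net (percentile 9.6). With measured genes above the 75th percentile only, the channel list lay at percentile 3.5 and the late plasticity list at percentile 11.2. On array 1 the 3' to 5' ratios were 4.85 for Gapdh, 2.48 for Actb and 11.3 for Pcx, against 4.47, 2.57 and 3.19 on array 3.

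Meningeal and fibroblast markers were higher on array 1 by 0.34 against -0.02 (17 of 26 higher), with Ptgds at 9423, 4917 and 6360 on arrays 1, 2 and 3, but lay at percentile 97.7 with the mean of a gene's probe sets and percentile 84.7 without probe sets of shared or cross-matching type. Oligodendrocyte genes departed on array 2 by -0.14 against 0.12 (8 of 18 higher), with Mobp at 17457, 10524 and 15898. None of the 3 other Mobp probe sets above the floor singled out the same array in the same direction. Mbp (6869, 8656 and 6813) and Qdpr (4353, 6782 and 3741) were highest on array 2. With the floor at the 40th percentile the oligodendrocyte list lay at percentile 8.8, with the mean of a gene's probe sets at percentile 7.2, above the 75th percentile at percentile 34.7 and with random lists not matched on level at percentile 8.8. Blood cell markers departed on array 3 by 0.47 against -0.02 (10 of 18 higher), with Camp, an antimicrobial peptide of granulocytes, at 182, 105 and 317, while the globin gene Hba-a1 was at 2496, 3033 and 1988. The AMPA, NMDA and kainate list departed on array 3 by -0.40 against -0.10 (7 of 22 higher), while 36.4% of all measured genes were higher on array 3 after scaling. With measured genes above the 75th percentile only, it departed by -0.24 net, at percentile 2.0. With quantile normalization the oligodendrocyte, blood and glutamate receptor departures lay at percentiles 5.1, 98.4 and 1.1. The blood departure was 0.05 net (percentile 66.9) with a floor at the 40th percentile and 0.40 (percentile 95.4) with a floor at the 5th. Without sample 1 the oligodendrocyte departure was -0.10 net and without sample 3 -0.12, and without sample 2 the blood departure was 0.07 and the glutamate receptor departure -0.09, all inside the 1st to 99th percentile. In all, 12 of 96 list and array pairs lay beyond the limits, where 1.9 would by chance for independent lists.

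**Figure D2:**
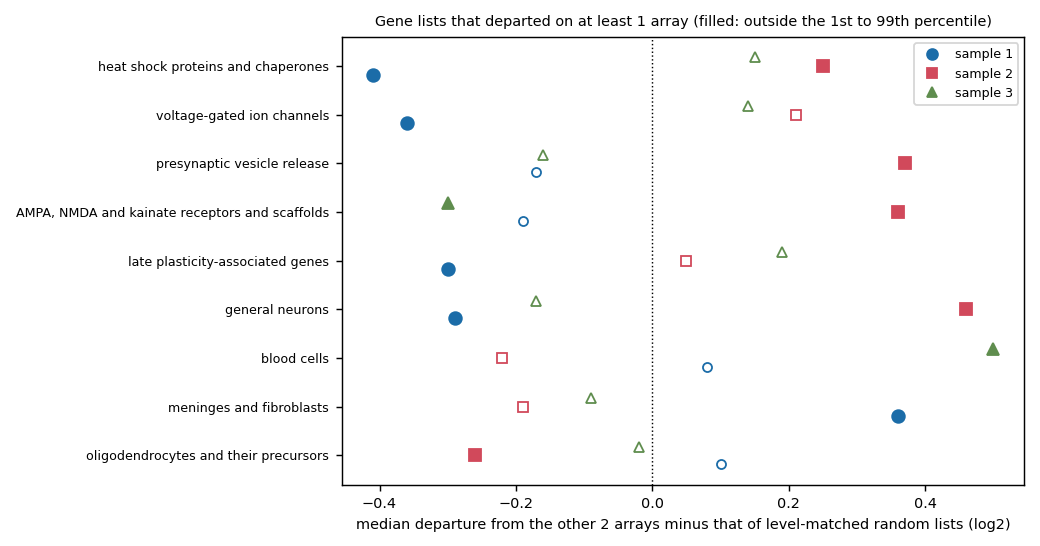
Departure of each sample from the mean of the other 2 arrays, as the list median minus that of level-matched random lists (horizontal axis, log2), for the 9 gene lists beyond the 1st or 99th percentile on at least 1 array; filled symbols are beyond these limits. General neuron, presynaptic and glutamate receptor lists lie at 0.46, 0.37 and 0.36 in sample 2, and the chaperone list at -0.41 in sample 1.

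Single genes that set 1 sample apart mostly rested on 1 probe set. On array 1 the lowest departures were Junb (-2.82), the carbonyl reductase Cbr3 (-2.51), Anxa2 (-2.42), Stk11ip (-2.39) and the farnesyltransferase subunit Fntb (-2.36), and the highest were adenosine deaminase, Ada (2.71), the imprinted noncoding RNA Meg3 (2.47), Hebp1 (2.38), the lysosomal Laptm4a (2.23) and the dynein light chain Dynll2 (2.21). Laptm4a was at 11174, 2487 and 2288 on arrays 1, 2 and 3, Meg3 at 2914, 767 and 360 and Dynll2 at 5437, 1694 and 815, and the other probe set of Meg3 and of Dynll2 singled out the same array in the same direction, as did another of Ada for its low value on array 2. On array 2 the highest were Rex1bd (3.45), Cherp (2.53), Nnat (2.46), the transcription factor Mef2c (2.44) and Pycrl (2.27), and the lowest were Ada (-3.86), Snrp1c-ps2 (-2.93), Bhmt (-2.47), Myoz1 (-2.31) and Chst3 (-2.28). Nnat, an imprinted membrane protein gene, was at 725, 4880 and 1082. On array 3 the lowest were Pycrl (-3.31), Arfgap2 (-3.20), Akap8l (-3.08), Mef2c (-2.71) and Wdr5 (-2.59), and the highest were Apoa5 (2.08), Cbr3 (1.69), Asb6 (1.67), Col9a1 (1.63) and Stk11ip (1.60). Of the 3 other Mef2c probe sets above the floor, 1 singled out the same array in the same direction, and without sample 2 the brightest Mef2c probe set gave 0.97 on array 3. Mef2c departed there by -0.97 with the mean of its probe sets and by -1.49 with a floor at the 40th percentile. Without probe sets of shared or cross-matching type Apoa5 departed by 0.00.

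Lists differed in which member varied most. The widest measured members were Crym among CA1 genes (1024, 2169 and 1060 on arrays 1, 2 and 3), the water channel Aqp4 among astrocyte genes (663, 2143 and 937), Vtn among vascular genes (331, 292 and 53.0), Cx3cr1 among microglial genes (198, 584 and 440), Gabra2 among GABA-A receptors (178, 827 and 869) and Grid1 among glutamate receptors (288, 651 and 77.3). Of the 30 different genes that are widest in their lists, 20 were highest in sample 2, with or without scaling. Of all 4863 measured genes, 45.7% were highest there after scaling and 31.8% without it.

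**Figure D3:**
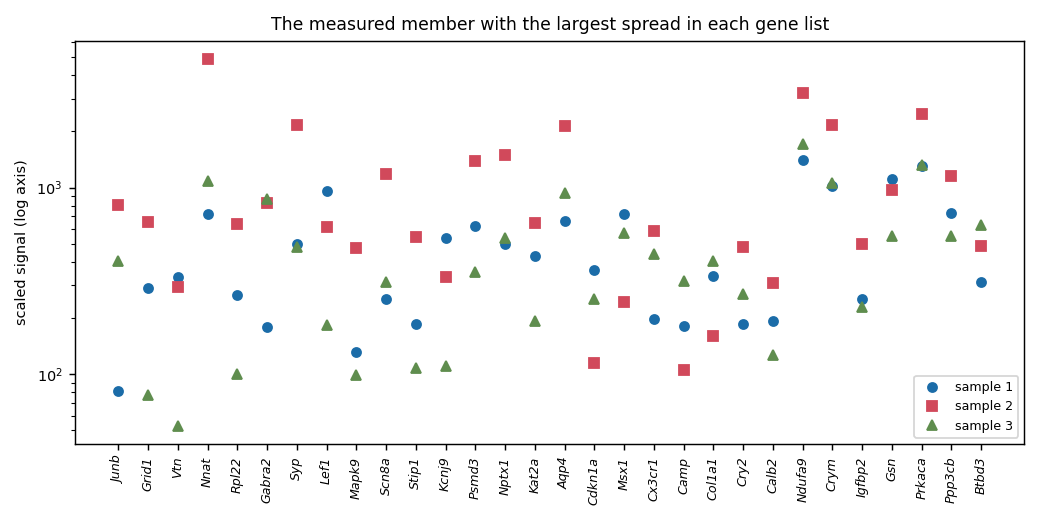
Scaled intensity (vertical log axis) in each of the 3 samples (symbols) of the measured member with the largest SD in each gene list, 30 genes in all, ordered from the widest (Junb) to the narrowest. Sample 2 is highest for 20 of the 30 genes.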

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

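Of the alternatives, only the removal of overlapping list members was chosen after the results were seen, and it left the presynaptic (0.37 on array 2), glutamate receptor (0.37 on array 2) and late plasticity (-0.30 on array 1) departures past their limits. From the late plasticity list only the overlap with the heat shock list was removed. Its 3 members shared with general neurons stayed in. The lowest correlation between arrays was 0.910 with a floor at the 5th percentile, 0.960 at the 40th and 0.925 over measured probe sets, and 0.933 to 0.938 when leaving out a replicate. The 889 probe sets over 2-fold became 3617 of 12422 with no filter, 236 of 3106 above the 75th percentile, 2697 with a 1.5-fold limit, and 284 to 501 with 2 arrays, where fewer arrays give smaller ranges by construction. Lists with wide spread numbered 1 in place of 2 with quantile normalization, without probe sets of shared or cross-matching type, above the 75th percentile, and with random lists not matched on level, and 0 to 4 when leaving out a replicate (0 without replicate 2). The 1 was general neurons, except with random lists not matched on level, where it was the endothelial and pericyte list. Departing list and array pairs numbered 5 in place of 12 above the 75th percentile and 6 to 14 with 2 arrays, where 1 list counts on both arrays as mirror images; the 6 came without replicate 2. Lists dimmer than random lists numbered 0 to 1 when leaving out a replicate, the 1 being blood cells without replicate 3. Brighter lists numbered 8 to 11 over all alternatives. Mef2c on array 3 lay between -3.44 and 0.97 when leaving out a replicate, against -2.71 with all 3; the 0.97, without replicate 2, comes from another probe set that is then the brightest. It was -0.97 with the mean of its probe sets and -1.49 with a floor at the 40th percentile. The cause of these changes was not tested, apart from those the construction gives. Of 109 departures of lists under other settings 93 stayed past their limit and 16 did not, and of 24 with a replicate left out 16 did and 8 did not. Levels of named genes were counted as moved in 55 cases under other settings and as the same in 718. Levels of lists were counted as moved in 30 cases and as the same in 162. No paired analysis was possible because there is only 1 group. The table has no background measurement, so what signal over background limits could not be assessed.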

Other observations

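The histone acetylation and chromatin list stood at 1.33 ± 0.06 (22 of 32 genes measured), above the 99th percentile of random lists on all 3 arrays, with the corepressor Trim28 at 5530 ± 596, the histone-binding Rbbp7 at 3030 ± 282 and the deacetylase Hdac5 at 2022 ± 649. The acetyltransferase Kat2a was its widest measured member, at 430, 648 and 193 on arrays 1, 2 and 3. The circadian list stood at 0.54 ± 0.11 (14 of 18), with the transcription factor Tef at 2799 ± 791 and the kinases Csnk1d at 2268 ± 235 and Csnk1e at 1124 ± 401, and Cry2 at 185, 477 and 270. The MAP kinase list stood at 0.53 ± 0.18 (23 of 33), with Mapk10 at 5172 ± 491, the exchange factor Rasgrf1 at 2319 ± 606 and Map2k1 at 1994 ± 568, and Mapk9 at 131, 475 and 99.1. Neurotrophins and growth factors stood at -0.20 ± 0.10 (16 of 28), with Bdnf at 2236 ± 504, Pdgfa at 1605 ± 208 and Igf2 at 1541 ± 487. The growth factor list departed on array 1 by -0.24 net of random lists, with 8 of 26 genes higher, at percentile 1.02, just inside the limit.

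Among genes chosen after their values were seen, Per1, a clock gene that activity also induces, was at 365, 377 and 384 on arrays 1, 2 and 3, Jun at 463, 486 and 486 and Clock at 310, 330 and 322, each with an SD of 0.05 or less on the log2 scale. Fos was at 271 ± 45.2, Fosb at 497 ± 77.1 and Nr4a1 at 601 ± 86.5. The probe set of Camk2a, which encodes an abundant kinase of pyramidal neurons, was at 49.9, 170 and 60.6 on arrays 1, 2 and 3, below the limit for measured genes. The 9 hybridisation control probe sets were 1.32 to 1.85 times as bright on array 3 as on the mean of the other 2 arrays, with a median of 1.60.

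Of the tests below, those of the share of glia and vessels, of the 5' signal, with its floor, and of independent noise, by signs and by flipped signs, were chosen after the results were seen, and so was the rule that a test of other probe sets must be able to reach its limit. Apart from the share of glia and vessels, no biological explanation was tested, because the labels give 1 group.

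General neuron, presynaptic and glutamate receptor genes were higher in sample 2, with a median departure of 0.51 over the 70 genes of these 3 lists against 0.13 in random lists, while CA1 (0.08 net), interneuron (0.17), calcium (0.11) and GABA-A (0.05) lists stayed within the limits, as did metabotropic and GABA-B receptors (0.28) and voltage-gated channels (0.21) more narrowly, and chaperones (0.25) passed them. Gene length argues little for it, since against random lists matched on gene span as well as level the departure stayed at the 100th percentile, and span correlated with departure at rho = 0.07 across these genes. The 14 other probe sets of 13 of the genes had a median departure of 0.51 against 0.10, at percentile 97.1. This lay within the limits, so the prediction written beforehand for noise of single probe sets was met. A departure as large as the pattern reaches only 96.7, also within the limits, so this test cannot decide. A count on the probe sets that define the pattern was chosen after the results were seen. It argues against noise that is independent between probe sets as the whole cause. There 56 of the 70 genes lay above the median of their class of level. By chance 0.0064 sets of 3 lists are expected with as many, over 29760 choices of lists, array and direction. In the single lists 23 of 28, 21 of 30 and 19 of 22 genes lay above that median. For single lists over 192 choices the number expected by chance is 0.0876, 4.11 and 0.0821. With the members' signs flipped it is 0.745, 0.424 and 0.0576 for the median and 0.00768, 0.0998 and 0.0173 for the mean. A share of noise in each list therefore stays open. A lower share of glia and vessels stays open too, because 0 of the 4 lists had a net departure whose 95% bootstrap interval lay below 0, and none had one above 0. The values were 0.07 (-0.16 to 0.25) for astrocytes, -0.26 (-0.37 to 0.09) for oligodendrocytes, 0.05 (-0.33 to 0.32) for microglia and -0.01 (-0.39 to 0.56) for endothelium. Each interval belongs to 1 array, so it covers spread among the genes of a list and not spread between samples. Less loss of signal towards the 5' end in sample 2 is a candidate explanation that stays open. Of the 4 control genes, 2 (Gapdh and Actb) had their highest 5' to 3' ratio there. Pcx did not (3' to 5' ratios of 11.3, 3.71 and 3.19 on arrays 1, 2 and 3), so the prediction that all 4 would was not met. Tfrc does not decide because its 5' probe set lay below the floor on arrays 1 and 3. That leaves the number at 2 or 3, where 2 or fewer would have counted against the explanation.

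Chaperones were lower in sample 1, with a median departure of -0.41 over 34 genes against 0.02 in random lists matched on span and level, at percentile 0.0, which argues against gene length (rho = -0.05). The 8 other probe sets of 7 of the genes had a median departure of -0.69 against -0.05, at percentile 0.5. This was past the limit written beforehand and argues against noise of single probe sets for these 7 genes. However, a departure of the size of the pattern would have reached only percentile 4.3. By the rule that the test must be able to reach its limit, it cannot decide for the list. The 26 of 34 genes below the median of their class alone leave 0.282 lists expected by chance. With the members' signs flipped, that number is 0.00576 for the median and 0 for the mean. A difference in stress or handling between the samples may lie behind the chaperone departure and was not tested. More loss of signal towards the 5' end in sample 1 stays open. Of the 4 control genes, 2 had their highest 3' to 5' ratio there (Gapdh 4.85 against 1.19 and 4.47 on arrays 2 and 3, Pcx 11.3 against 3.71 and 3.19). Actb did not (2.48 against 1.93 and 2.57), so the prediction that all 4 would was not met. A number of 2 or fewer would have counted against the explanation. Tfrc (14.0 against 3.45 and 7.78) does not decide because its 5' probe set lay below the floor on arrays 1 and 3. The members lower in sample 1 include Hspa5 (1484, 2498 and 2396 on arrays 1, 2 and 3) and, chosen after their values were seen, Hsp90b1 (1876, 3122 and 2755), Dnajb9 (217, 477 and 448) and the inducible Hspa1b (307, 606 and 475).

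Departures of single genes may be noise of the probe set rather than a difference in RNA. Across 246 genes with at least 2 probe sets of plain type, the departures of 2 probe sets of 1 gene correlated at r = 0.11, 0.04 and -0.10 on arrays 1, 2 and 3, against a 99th percentile of 0.15 for probe sets of different genes. The prediction for noise, r under 0.1 on each array, was met on 2 of 3. The opposite prediction, r over 0.1 and above that 99th percentile on each array, was met on none, at percentiles 95.3, 72.5 and 6.2. The test therefore leaves noise of the probe set open, with -0.10 as the lowest value. Where the first probe set departed by over 2-fold, the second had the same sign in 10 of 13 genes on array 1, 13 of 16 on array 2 and 3 of 8 on array 3, and departed by over 2-fold the same way in 1, 2 and 0.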
